A study of Homo sapiens with 10 samples.

How the data were processed

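RNA from 22Rv1 cells was selected for polyadenylated transcripts and sequenced with strand information, in 10 libraries of 5 groups with 2 biological replicates each. Per the submitters' processing notes, hg38, Bowtie2 and RSEM were used, with no version or settings, and neither the annotation release nor any filter on genes is stated. The series holds 1 table of 16623 genes with Entrez identifiers and symbols, of which 14 identifiers are not Entrez numbers. Per the file headers, the deposited table gives a read count, TPM and FPKM for each library. The read counts were read as the expected counts that RSEM gives, since 998 genes (6.0%) have a fractional value. The authors also gave a scaled signal, which was checked against the counts: on genes with 100 counts or more, it equals the expected count times 1 factor per library, from 0.918 to 1.114, within 1.0%. The deposited group means of these units were not used. The TPM and FPKM values by the authors were not used for any comparison. No column belongs to a sample outside the series (0 such columns).

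Expected counts were rounded to whole numbers. Genes were kept by filterByExpr with a minimum count of 10, which left 13248, and libraries were scaled by TMM. All 10 libraries entered 1 fit with a coefficient per group, and 8 contrasts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 9.4%, with 5 residual and 8.1 prior degrees of freedom. Fold changes are log2 values with a standard error (SE) derived as their size over the square root of the F statistic. The test gives no SE of its own, so this value is approximate. Levels are CPM, counts scaled to the TMM-adjusted library total, as mean and SD of 2 libraries. Totals of 13419660 to 15722502 counts per library and 2 libraries per group set the precision. For genes with 3 counts or fewer over a group, the ratio of depth-adjusted counts is given with its exact 95% Clopper-Pearson interval. These intervals cover counting error only, and reads without molecular identifiers are not independent molecules.

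The comparisons, the gene lists, the rule for named genes and the alternative analyses were fixed before the data were examined. The 18 lists were androgen-induced genes, androgen-repressed genes, AHR target genes, NRF2 target genes, type I interferon response, G1/S replication genes, G2/M mitotic genes, sterol synthesis genes, fatty acid synthesis genes, unfolded protein and integrated stress response (called the stress response list), p53 target genes, PARP7 and receptor components, neuroendocrine markers, luminal prostate markers, basal prostate markers, stromal, endothelial and immune markers, reference genes and heat shock genes. Each list was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, for lists with 5 or more tested members, two-sided and adjusted over the lists within a comparison. Of 144 such tests 53 passed, and 2 passed with a correlation estimated from the data, the androgen-induced and sterol synthesis lists for DHT against vehicle. The self-contained test fry was also run. Counts of members are given over all genes and adjusted over the list alone.

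In each main comparison the rule named 12 fixed genes, among them KLK3, KLK2, TMPRSS2, FKBP5, TIPARP, AHR, AHRR, CYP1A1, CYP1B1 and NQO1. It added the 6 largest rises and the 6 largest falls among called genes with a mean of 2 CPM or more in a group compared, a usable symbol and libraries that did not overlap between the groups. It added up to 4 members of each list with the smallest adjusted p past the threshold, or up to 2 where none passed. In the other 4 comparisons it named the fixed genes and 5 rises and 5 falls. The rule gave 334 results, 215 of them past the threshold, and the text names a part of them.

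The alternative analyses were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a stricter filter of 5 CPM in 2 libraries, a replicate block, a fit of only the groups compared, an estimated correlation for the lists, and leaving out each library in turn. The stricter filter and the fit of only the groups compared were not run for the named genes or the lists. Where 1 library remained in a group, it is assumed to vary like the other groups. After the data were seen, a fit was added with trends of log2 CPM in transcript length and GC content removed from each library by lowess through edgeR offsets. Length and GC content came from GENCODE 29 transcripts, with a value for 97.9% of the tested genes. Chromosome positions came from the RefSeq annotation of GRCh38.p14, the assembly that hg38 names, joined by Entrez identifier.

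The overlap of effects was given as a correlation across genes and as shared calls beside the product of the lists' sizes over the genes tested, and 20 simulated data sets with no change gave the values that shared libraries produce. The methods were tested on simulated data with the depth of these libraries and a spread per gene that all groups share. Except for a length trend in the last test, the wider disagreement of the tapinarof libraries was not simulated. Recovery for tapinarof and the interaction may thus be overstated. For tapinarof in DHT edgeR found 38% of seeded 1.5-fold changes, 84% of 2-fold, 93.9% of 3-fold and 96% of 4-fold changes, with 11 false calls in 166. For the interaction it found 20.8%, 69.4%, 88% and 90% of the same folds, with 11 false calls in 144. For tapinarof in DHT camera called 1 of 1 seeded list and 0 of 17 unchanged lists. These lists held random genes with independent counts, so they do not show the rate of false calls where list members vary together. Removing a simulated length trend changed the recovery of 150 seeded genes from 132 to 135, with 9 false calls in 157 before and 12 in 174 after.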

Results

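Messenger RNA was sequenced from 22Rv1, an established human prostate carcinoma cell line. The cells were kept without hormone for 3 days and then treated for 48 hours. The 10 libraries formed 5 groups of 2, which the labels call biological replicates. The groups were vehicle, 5 nM dihydrotestosterone (DHT), DHT with 100 nM RBN-2397, DHT with 100 nM tapinarof, and DHT with both compounds at 100 nM each. RBN-2397 is an inhibitor of PARP7, a mono-ADP-ribosyltransferase encoded by TIPARP. Tapinarof is an agonist of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. Estimated counts totalled 15618023 and 14597719 in the vehicle libraries, 14520593 and 15722502 with DHT, and 15366147 and 15516311 with RBN-2397. They totalled 15407163 and 13419660 with tapinarof, and 15541743 and 15267550 with the combination. Of 16623 genes in the table, 13248 were tested. With 2 libraries per group, the median standard error of a log2 fold change was 0.14 in the 7 comparisons of groups and 0.20 in the interaction.

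On the 2000 genes with the highest variance, the first principal component held 60.8% of the variance and separated vehicle from the other groups. The second held 14.3%, with both DHT libraries and both tapinarof libraries at one end and the combination at the other. Libraries of 1 group correlated across genes at r = 0.99 with vehicle, 0.993 with DHT, 0.994 with RBN-2397, 0.985 with tapinarof and 0.994 with the combination. Genes are not independent replicates, so these are descriptions of spread. The tapinarof pair stood apart from the others. Its log2 ratio of library 1 over library 2 had an SD of 0.42 across genes, against 0.28 to 0.33 in the other pairs. That ratio fell with transcript length (Spearman rho across genes = -0.50), from a median of 0.30 in the shortest of 10 length bins to -0.32 in the longest. All groups share the same estimate of spread in the main fit, so this pair enters it in every comparison, also in those without tapinarof. Ribosomal protein genes took 9.95% of the counts in tapinarof library 1 and 8.02% in library 2. Their share was 9.03% and 9.66% with vehicle, 7.37% and 7.87% with DHT, 7.79% and 7.86% with RBN-2397, and 7.96% and 6.97% with the combination.

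**Figure D1:**
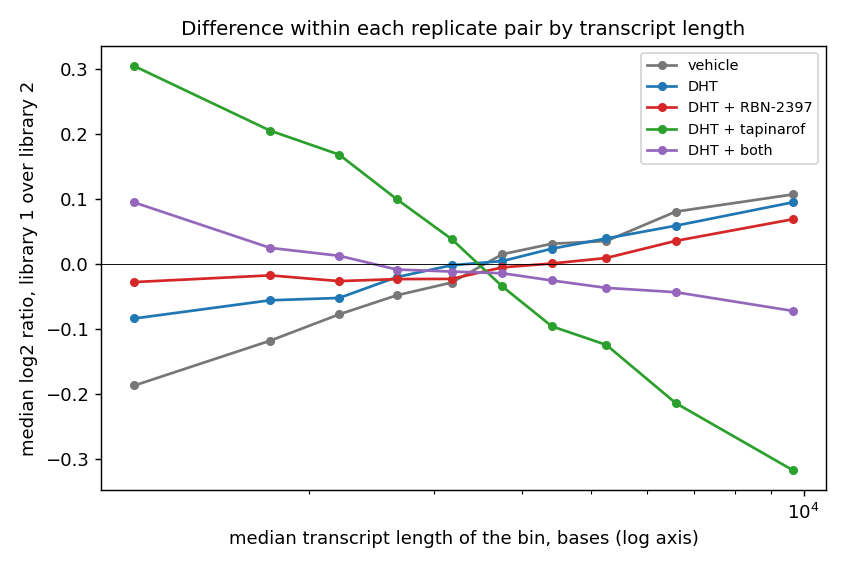
Median log2 ratio of CPM in library 1 over library 2 of each group (vertical axis) for 10 bins of genes by median transcript length in bases (horizontal log axis), with 1 line per group. The tapinarof line runs from 0.30 at 1132 bases to -0.32 at 9646 bases, and the vehicle line from -0.19 to 0.11.

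DHT was compared with vehicle to ask which genes the androgen changed after hormone deprivation. FKBP5, an immunophilin gene induced by androgen, rose from 158 ± 23.3 to 1242 ± 65.1 CPM (counts scaled to the library total; mean ± SD, n = 2), a log2 fold change of 2.98 (SE 0.12). Other androgen-induced genes rose with it: the metalloreductase STEAP4 by 4.89 (SE 0.22), the transcription factor MAF by 3.94 (SE 0.21) and the transporter SLC45A3 by 3.18 (SE 0.14). The kallikrein genes rose less, KLK3 (prostate-specific antigen) by 0.97 (SE 0.17) and KLK2 by 0.98 (SE 0.13). TIPARP rose by 1.05 (SE 0.12), from 18.0 ± 2.43 to 37.2 ± 1.53 CPM. TMPRSS2 measured 0.05 (adjusted p = 0.844), AHR -0.28 (0.304), AHRR 0.11 (0.815), CYP1A1 0.00 (0.992) and CYP1B1 -0.07 (0.862) in edgeR. On the hg38 assembly KLK3 (Entrez 354) lies on chromosome 19 at 50854915 to 50860764 and FKBP5 (Entrez 2289) on chromosome 6 at 35573590 to 35728583. TIPARP (Entrez 25976) lies on chromosome 3 at 156674590 to 156706770, and all 3 are annotated as protein-coding genes.

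Of the 41 androgen-induced genes tested, 35 rose and 0 fell with DHT by edgeR, or 36 and 0 adjusted over the list alone, with a median log2 fold change of 0.98. The list passed camera (adjusted p = 1.78e-36), also with an estimated correlation (adjusted p = 0.00745). Of 16 androgen-repressed genes, 9 fell and 1, UGT2B28, rose, the same counts as when adjusted over the list alone. The glucuronosyltransferase UGT2B15 fell by 2.20 (SE 0.11), the disaccharidase SI fell by 2.88 (SE 0.17) and FOLH1, which encodes prostate-specific membrane antigen, fell by 1.75 (SE 0.12). This list passed downward (camera adjusted p = 1.09e-07; adjusted p = 0.0678 with an estimated correlation). UGT2B28 held 2 counts over the vehicle group and 140 and 131 in the DHT libraries, a depth-adjusted ratio of 140 (95% exact interval 38.3 to 1160, counting error only). Large falls outside the lists included the galactosyltransferase B3GALT5 at -5.17 (SE 0.34), the cadherin CDH10 at -4.67 (SE 0.30) and the kinase BMX at -4.28 (SE 0.45).

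Of 23 sterol synthesis genes, 11 rose and 0 fell with DHT (15 and 1 adjusted over the list alone), among them INSIG1 by 0.66 (SE 0.10), ACAT2 by 0.64 (SE 0.09) and FDFT1 by 0.50 (SE 0.09). Of 14 fatty acid synthesis genes, 6 rose and 0 fell (7 and 1 over the list alone), with the elongase ELOVL5 up by 2.04 (SE 0.12), FASN by 1.18 (SE 0.12), FADS1 by 0.69 (SE 0.09) and FADS2 by 0.67 (SE 0.10). The sterol list passed camera (adjusted p = 9.37e-08; adjusted p = 0.0131 with an estimated correlation), and the fatty acid list passed with the preset correlation (adjusted p = 0.000127; adjusted p = 0.124 with an estimated correlation). Among 25 G1/S replication genes 7 rose and 0 fell, or 12 and 0 adjusted over the list alone, with the ribonucleotide reductase subunit RRM2 up by 0.59 (SE 0.10). Among 30 G2/M mitotic genes 7 rose and 0 fell, or 14 and 0 over the list alone, with a median of 0.28. Both cell cycle lists passed upward, G1/S at 2.25e-06 (adjusted p = 0.0927 with an estimated correlation) and G2/M at 1.23e-07 (adjusted p = 0.0794 with an estimated correlation). With trends in transcript length and GC content removed, 18 sterol, 9 fatty acid, 15 G1/S and 21 G2/M genes rose, and 1 sterol and 1 fatty acid gene fell.

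Of 10 neuroendocrine markers, 4 fell and 0 rose with DHT, over all genes and adjusted over the list alone, including the chromogranins CHGB at -1.42 (SE 0.17) and CHGA at -1.5 (SE 0.27) and the enolase ENO2 at -0.61 (SE 0.11). Of 7 basal prostate markers, 4 fell and 1, the keratin KRT15, rose (5 and 1 over the list alone), with CAV1 down by 2.21 (SE 0.32) and the integrin ITGB4 by 2.13 (SE 0.38). The neuroendocrine list passed at 0.0034 (adjusted p = 0.181 with an estimated correlation) and the basal list at 0.0029 (adjusted p = 0.124 with an estimated correlation). With trends removed 6 neuroendocrine markers fell and 1 rose. Luminal markers went both ways: the keratins KRT8 and KRT18 rose by 1.01 (SE 0.11) and 0.87 (SE 0.12), while the phosphatase ACP3 fell by 1.87 (SE 0.15) and GATA2 by 1.16 (SE 0.12). In that list of 11, 2 rose and 3 fell (2 and 4 over the list alone), and it did not pass (adjusted p = 0.142).

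Of 16 AHR target genes, 5 rose and 1, ABCG2, fell, with the same counts adjusted over the list alone, and the list passed upward at 0.00945 (adjusted p = 0.124 with an estimated correlation). Those that rose included the glucuronosyltransferase UGT1A1 by 3.40 (SE 0.29), the actin-severing protein gene SCIN by 0.99 (SE 0.11), the amino acid transporter SLC7A5 by 0.66 (SE 0.11) and TIPARP. The unfolded protein and integrated stress response list passed upward at 0.00736 (adjusted p = 0.297 with an estimated correlation), with 2 of 24 members up and 0 down (1 and 0 over the list alone), among them DDIT4 by 0.75 (SE 0.13). NRF2 targets were split, with 4 up and 3 down of 20, the same over the list alone. GCLC, a subunit of the enzyme that starts glutathione synthesis, rose by 1.08 (SE 0.11), and the aldo-keto reductases AKR1C1 and AKR1C2 fell by 2.41 (SE 0.24) and 2.09 (SE 0.14). That list had a median of 0.04 and a mean of -0.10 and did not pass (adjusted p = 0.563). Type I interferon genes were split as well, with 2 up and 4 down of 16 (2 and 5 over the list alone; adjusted p = 0.436), such as HERC5 at 1.09 (SE 0.14) and IFIH1 at -1.48 (SE 0.22). With trends removed 7 genes of the stress response list rose and 0 fell, and 7 NRF2 targets rose and 4 fell. AKR1C1, AKR1C2, UGT1A1, UGT2B15 and FOLH1 have fractional counts, so reads shared with related genes were divided by estimate.

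Of 20 p53 targets, TNFRSF10B rose by 0.97 (SE 0.11), CDKN1A rose by 0.55 (SE 0.11) and BTG2 fell by 0.67 (SE 0.12), with the same counts of 2 and 1 over the list alone (median -0.01, mean 0.04, adjusted p = 0.544). Among 19 PARP7 and receptor components 3 rose and 0 fell, also over the list alone (adjusted p = 0.638, tested direction up, median -0.01). Of 5 stromal, endothelial and immune markers tested, 1 rose and 1 fell, also over the list alone (median -0.46, mean 0.05, adjusted p = 0.563). Of 12 reference genes 2 rose and 0 fell, or 3 and 0 over the list alone (adjusted p = 0.142). Of 13 heat shock genes 0 passed edgeR, the same over the list alone (adjusted p = 0.362). With trends removed 5 p53 targets rose and 4 fell, 4 PARP7 and receptor components rose and 2 fell, 3 reference genes rose and 1 fell, and 4 heat shock genes rose and 0 fell. In all, edgeR called 1991 of the 13248 genes, 851 up and 1140 down, with 243 up and 457 down by 2-fold or more. The count was 1006 without DHT library 1, 966 without DHT library 2, 3002 without either tapinarof library, and 3857 with trends in transcript length and GC content removed, which was chosen after seeing the data.

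**Figure D2:**
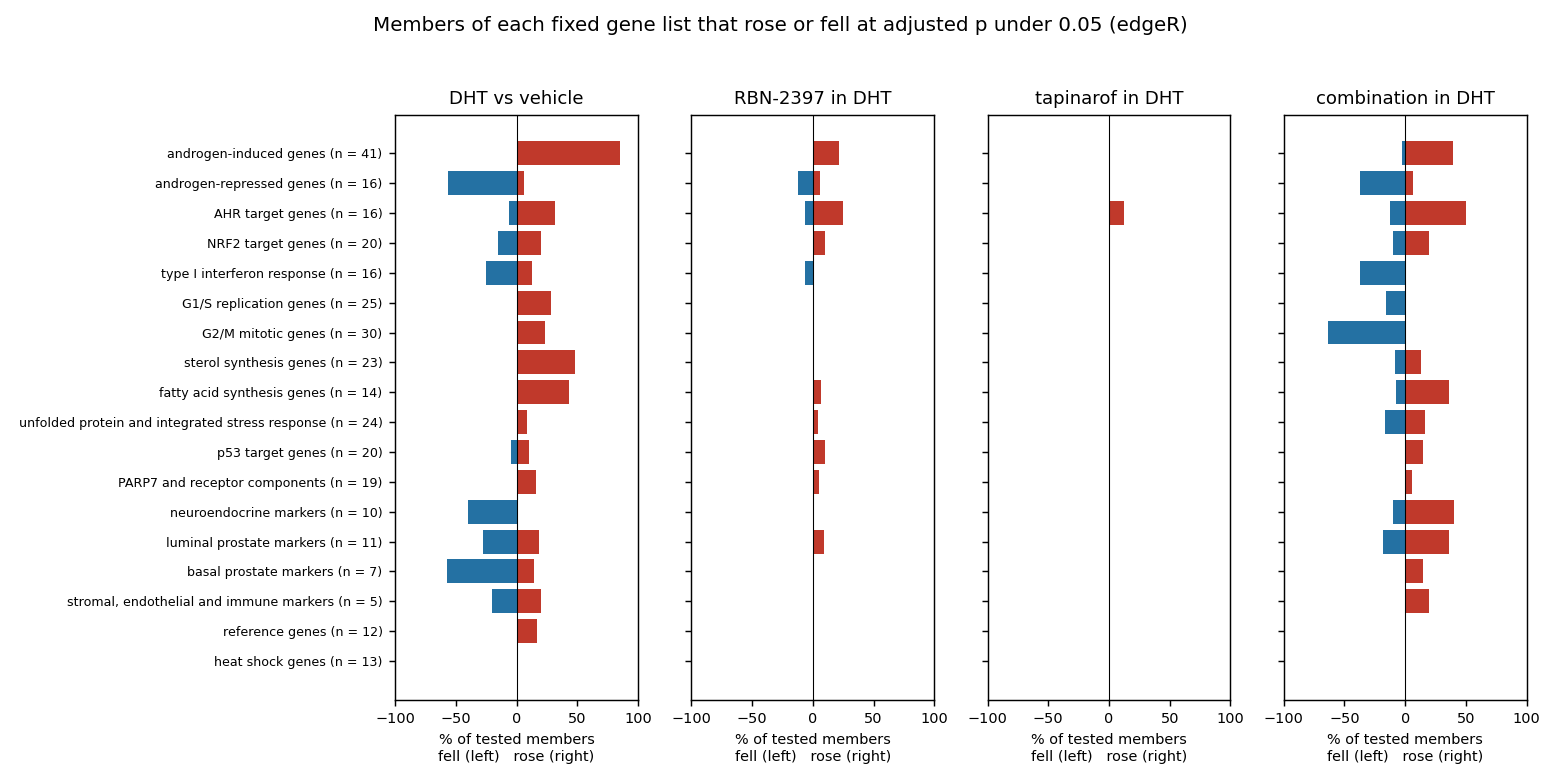
Bars give the percentage of tested members of each of the 18 fixed gene lists that rose (right, red) or fell (left, blue) at an adjusted p under 0.05 in edgeR, in 4 panels for DHT against vehicle and for RBN-2397, tapinarof and the combination in DHT. The bar of the 41 androgen-induced genes stands for 35 that rose with DHT, and that of the 30 G2/M mitotic genes for 7 that rose with DHT and 19 that fell with the combination.

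RBN-2397 was added to DHT to ask what PARP7 inhibition changes in androgen-treated cells. KLK3 rose from 19.7 ± 0.170 to 68.8 ± 0.888 CPM (mean ± SD, n = 2), a log2 fold change of 1.80 (SE 0.15), and TIPARP, the gene of the inhibited enzyme, rose from 37.2 ± 1.53 to 111 ± 3.23 CPM (1.58, SE 0.11). CYP1A1, the monooxygenase gene that AHR activates, rose by 3.28 (SE 0.19), from 5.77 ± 0.188 to 55.9 ± 0.272 CPM. SCNN1G and SCNN1B, subunits of the epithelial sodium channel, rose by 3.29 (SE 0.21) and 2.81 (SE 0.27), the histone gene H4C8 by 3.03 (SE 0.40) and the tubulin gene TUBA3D by 2.85 (SE 0.17). The stress-induced cytokine GDF15 rose by 1.90 (SE 0.18). TUBA3D has fractional counts, so its level includes reads divided among related tubulins by estimate. FKBP5 measured 0.13 (adjusted p = 0.729), TMPRSS2 -0.09 (0.848), AHR 0.01 (0.989), AHRR 0.20 (0.820), CYP1B1 -0.08 (0.927) and NQO1 -0.24 (0.458) in edgeR. CYP1A1 (Entrez 1543) lies on chromosome 15 at 74719542 to 74725528 and SCNN1G (Entrez 6340) on chromosome 16 at 23182745 to 23216883, on hg38.

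**Figure D3:**
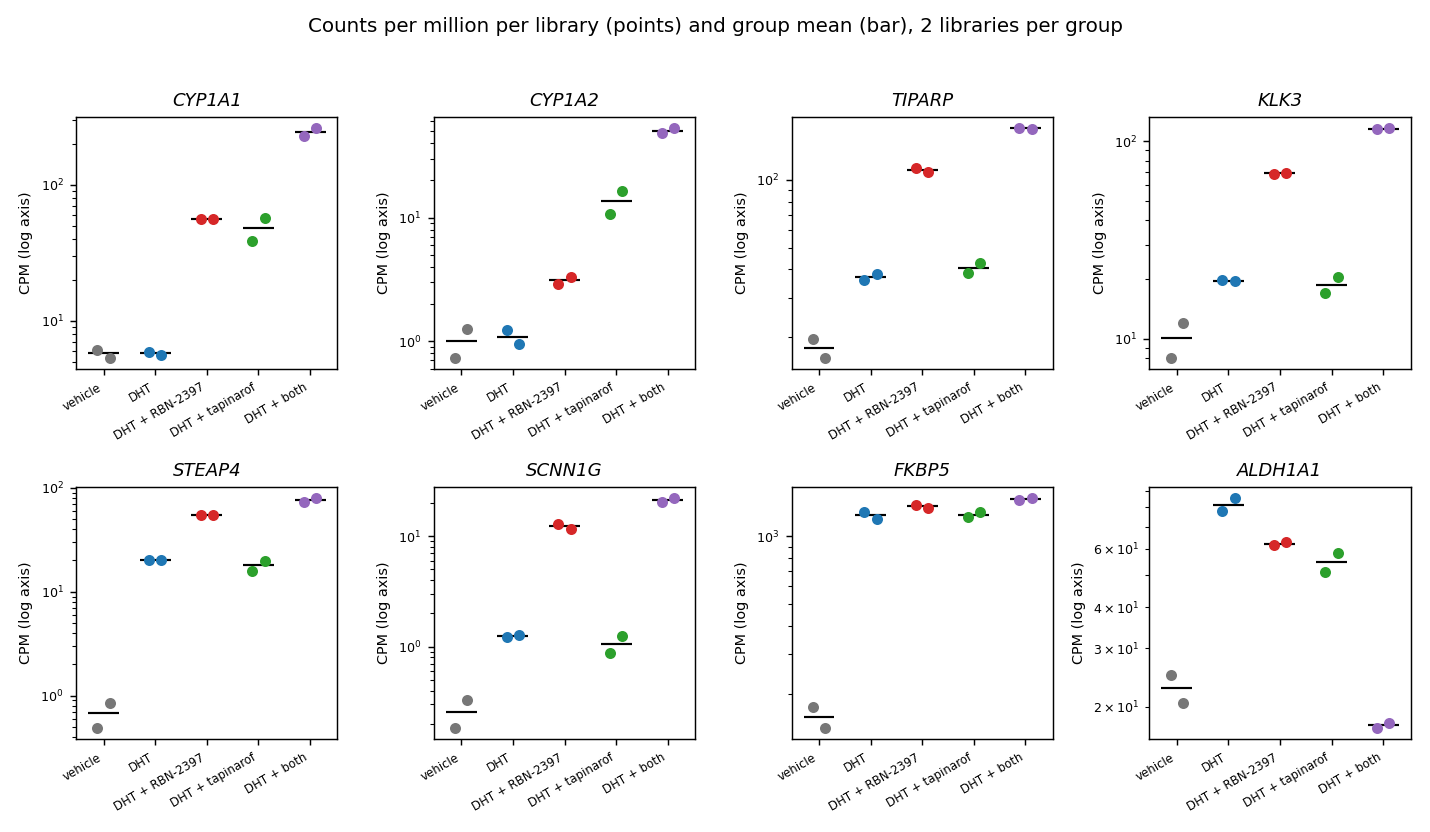
CPM on a log axis for 8 genes, 1 panel each, in the 5 groups, with a point for each library and a bar at the mean. KLK3 means are 10.1, 19.7, 68.8, 18.8 and 116 CPM in vehicle, DHT, RBN-2397, tapinarof and the combination.

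Of the 41 androgen-induced genes, 9 rose and 0 fell with RBN-2397, or 14 and 0 adjusted over the list alone, with a median of 0.13. They included STEAP4 at 1.45 (SE 0.13), the receptor feedback gene ERRFI1 at 1.03 (SE 0.09), NDRG1 at 1.02 (SE 0.09) and KLK2 at 0.89 (SE 0.13). The list passed upward at 7.51e-10 (adjusted p = 0.116 with an estimated correlation). Among 16 androgen-repressed genes 2 fell and 1 rose (4 and 1 over the list alone), with FOLH1 at -0.61 (SE 0.12) and UGT2B28 at 1.21 (SE 0.16), and the list passed downward at 0.0197 (adjusted p = 0.255 with an estimated correlation; 0.0995 without RBN-2397 library 2). Of 16 AHR targets 4 rose and 1 fell (4 and 2 over the list alone; adjusted p = 0.0109, or adjusted p = 0.175 with an estimated correlation). The stress response list passed upward at 2.49e-06 (adjusted p = 0.156 with an estimated correlation), with 1 of 24 up, DDIT4 at 0.80 (SE 0.12), and 4 over the list alone. The p53 list passed upward at 0.00749 (adjusted p = 0.116 with an estimated correlation), with GDF15 and 1 other gene up, also over the list alone. Sterol synthesis genes passed upward at 0.00752 (adjusted p = 0.116 with an estimated correlation) and G2/M genes downward at 0.00145 (adjusted p = 0.180 with an estimated correlation), with 0 members past edgeR over all genes or over the list alone in either. Their medians were 0.12 and -0.14. Type I interferon genes passed downward at 0.0311 (adjusted p = 0.180 with an estimated correlation; 0.0765 without RBN-2397 library 1), with 0 up and 1 down of 16, or 1 and 2 over the list alone. The other 10 lists did not pass, with an adjusted p of 0.0946 or more, but with length and GC trends removed G1/S genes passed downward (0.0111; adjusted p = 0.209 with an estimated correlation). That removal gave 12 androgen-induced genes up and 1 down, 1 androgen-repressed gene up and 4 down, and 4 stress response and 2 sterol synthesis genes up.

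In all, edgeR called 199 genes with RBN-2397, 175 up and 24 down, and 87 of those that rose and 4 of those that fell changed by 2-fold or more. Falls included the cadherin CDH17 at -0.89 (SE 0.17) and TEX45 at -1.17 (SE 0.22). The calls of FOLH1, CDH17 and TEX45 ended without either DHT library or either RBN-2397 library (adjusted p from 0.0599 to 0.264), and those of KLK2 (0.0545) and DDIT4 (0.0802) without DHT library 2. The count was 82 and 76 without DHT library 1 or 2, 97 and 100 without RBN-2397 library 1 or 2, and 422 and 433 without tapinarof library 1 or 2. Fitted on only the DHT and RBN-2397 libraries it was 1005 (647 up and 358 down), and with length and GC trends removed 598 (411 up and 187 down).

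Tapinarof was added to DHT to ask what AHR activation changes in androgen-treated cells, and edgeR called 2 genes. CYP1A1 rose from 5.77 ± 0.188 to 47.8 ± 13.3 CPM (mean ± SD, n = 2), a log2 fold change of 3.05 (SE 0.19, adjusted p = 5.41e-06). CYP1A2, a monooxygenase gene on the same chromosome (15, at 74748845 to 74756607), rose from 1.09 ± 0.19 to 13.6 ± 3.96 CPM, or by 3.64 (SE 0.27, adjusted p = 3.19e-05). TIPARP, also an AHR target, measured 0.12 (adjusted p = 0.971), AHRR -0.02 (0.998), CYP1B1 0.24 (0.971) and NQO1 0.01 (0.998). Among androgen-regulated genes KLK3 measured -0.07 (0.977), KLK2 0.04 (0.982), FKBP5 0.01 (0.998) and TMPRSS2 -0.15 (0.971). The next members of the fixed lists by p were GCLC at 0.33 and GDF15 at 0.62 (both adjusted p = 0.971). A 0 count applies to the genes that fell: edgeR called 0, and 510 genes were at an unadjusted p under 0.05 in either direction, where chance gives 662. DESeq2 called 4 genes in all.

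AHR targets passed upward with tapinarof at 0.000125 (adjusted p = 0.183 with an estimated correlation; 0.113 without tapinarof library 2), with 2 of 16 up and 0 down, or 3 and 0 adjusted over the list alone. Another 3 lists passed downward with 0 members past edgeR over all genes or over the list alone. G2/M genes passed at 0.00877 (median -0.09; adjusted p = 0.523 with an estimated correlation), but not without tapinarof library 1 (0.0596) or 2 (0.113). Sterol synthesis genes passed at 0.0338 (median -0.07; adjusted p = 0.258 with an estimated correlation), but not without DHT library 2 (0.231) or tapinarof library 1 (0.0596) or 2 (0.276). Fatty acid synthesis genes passed at 0.0338 (median -0.09; adjusted p = 0.523 with an estimated correlation), but not without DHT library 1 (0.205) or 2 (0.0599) or tapinarof library 1 (0.709) or 2 (0.101), or with length and GC trends removed (0.0655). The other 14 lists had 0 calls and an adjusted p of 0.239 or more. The count of genes was 6 without tapinarof library 1 and 1117 without tapinarof library 2. The larger count rests on tapinarof library 1 alone for that group, where a trend with transcript length cannot be told apart from an effect of tapinarof. With length and GC trends removed, an alternative chosen after seeing the data, the count was 6. These added IGFBP3 at 0.58 (adjusted p = 0.00652), the interleukin receptor gene IL1R1 at 0.49 (0.00879), ST3GAL1 at 0.48 (0.00879) and the retinaldehyde dehydrogenase gene ALDH1A1 at -0.59 (0.0108), named after their values were seen.

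The combination of RBN-2397 and tapinarof was compared with DHT alone to ask what PARP7 inhibition and AHR activation change together. CYP1A1 rose from 5.77 ± 0.188 to 245 ± 21.8 CPM (mean ± SD, n = 2), a log2 fold change of 5.41 (SE 0.19), and CYP1A2 from 1.09 ± 0.19 to 50.5 ± 3.11 CPM (5.53, SE 0.25). KLK3 rose from 19.7 ± 0.170 to 116 ± 0.602 CPM (2.56, SE 0.15), and TIPARP from 37.2 ± 1.53 to 169 ± 0.208 CPM (2.18, SE 0.11). GDF15 rose by 2.95 (SE 0.18), STEAP4 by 1.92 (SE 0.13) and KLK2 by 1.21 (SE 0.13). ALDH1A1 fell by 2.22 (SE 0.13), from 81.6 ± 5.07 to 17.6 ± 0.401 CPM, and DPY19L2 fell by 2.01 (SE 0.37). FKBP5 measured 0.23 (adjusted p = 0.172), TMPRSS2 -0.22 (0.230) and AHR -0.01 (0.987) in edgeR. The cancer-testis gene CTAG1B had 0 counts in both DHT libraries, 281 and 935 with the combination, and 0 and 772 with vehicle, and its call ended without DHT library 1 (adjusted p = 0.125), DHT library 2 (0.132) or combination library 2 (0.146). Its reads are shared with CTAG1A, and the sum of both genes measured 0.38 (adjusted p = 0.195). The lysosomal gene LAPTM5, with 2 counts over the DHT group and 47 and 54 with the combination, gave a ratio of 51.1 (95% exact interval 13.8 to 427).

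Of 30 G2/M mitotic genes, 19 fell and 0 rose with the combination, or 25 and 0 adjusted over the list alone, with a median of -0.44. The kinase CDK1 fell by 0.55 (SE 0.09) and the kinetochore gene NUF2 by 0.67 (SE 0.13). The list passed downward at 2.09e-12 (adjusted p = 0.101 with an estimated correlation), and G1/S genes passed downward at 0.0067 (adjusted p = 0.277 with an estimated correlation), with 4 of 25 down and 0 up (5 and 0 over the list alone). Of 16 AHR targets 8 rose and 2 fell, the same over the list alone, with UGT1A1 up by 1.96 (SE 0.17), CYP1B1 by 0.95 (SE 0.18) and the receptor repressor AHRR by 0.88 (SE 0.22); the list passed at 0.00256 (adjusted p = 0.163 with an estimated correlation). Of 41 androgen-induced genes 16 rose and 1 fell (19 and 2 over the list alone), with ERRFI1 at 1.30 (SE 0.09) and NDRG1 at 1.28 (SE 0.09). That list passed upward at 3.14e-07 (adjusted p = 0.145 with an estimated correlation). Of 16 androgen-repressed genes 6 fell and 1 rose (8 and 1 over the list alone), with the secreted Wnt inhibitor DKK1 at -1.36 (SE 0.14), BCHE at -1.28 (SE 0.18), FOLH1 at -0.91 (SE 0.12) and UGT2B15 at -0.89 (SE 0.12). They passed downward at 0.000538 (adjusted p = 0.188 with an estimated correlation). Of 16 interferon genes 6 fell and 0 rose (7 and 1 over the list alone), and the list passed at 0.0355 (adjusted p = 0.224 with an estimated correlation), but not without vehicle library 1 (0.0501), tapinarof library 1 (0.0610) or combination library 1 (0.0587). With trends removed 9 G1/S and 27 G2/M genes fell, 22 androgen-induced genes rose and 4 fell, and 6 interferon genes fell and 1 rose.

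The other 12 lists did not pass with the combination, with an adjusted p of 0.105 or more, and their members went both ways. ELOVL5 rose by 0.98 (SE 0.11), FASN by 0.93 (SE 0.12), FADS1 by 0.68 (SE 0.09), FADS2 by 0.59 (SE 0.10) and the sterol reductase DHCR7 by 0.72 (SE 0.12). Among NRF2 targets GCLC rose by 1.07 (SE 0.10) and AKR1C2 by 1.51 (SE 0.14), and the cystine transporter SLC7A11 fell by 1.19 (SE 0.18). DDIT4 rose by 0.93 (SE 0.12), TNFRSF10B by 0.97 (SE 0.11), CDKN1A by 0.61 (SE 0.11) and KRT8 by 0.93 (SE 0.11). In all, edgeR called 1665 genes, 865 up and 800 down, with 230 up and 106 down by 2-fold or more. The calls of CDK1 and NUF2 ended without DHT library 2 (adjusted p = 0.0654 and 0.0683) or combination library 2 (0.0662 and 0.116), that of CYP1B1 without DHT library 1 (0.0717), and that of AHRR with the DESeq2 test (0.0659) or without DHT library 1 (0.151), DHT library 2 (0.0767) or combination library 2 (0.186). The count was 454 and 479 without DHT library 1 or 2, 3165 and 3184 without tapinarof library 1 or 2, 619 and 397 without combination library 1 or 2, 4638 when only the groups compared were fitted and 2601 with trends removed.

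RBN-2397 was also compared within tapinarof-treated cells, the combination against DHT with tapinarof. KLK3 rose by 2.63 (SE 0.15), from 18.8 ± 2.48 to 116 ± 0.602 CPM (mean ± SD, n = 2), KLK2 by 1.16 (SE 0.13), TIPARP by 2.06 (SE 0.11) and CYP1A1 by 2.36 (SE 0.15). ALDH1A1 fell by 1.64 (SE 0.13) and the potassium channel subunit KCNMB2 by 2.19 (SE 0.33). PDZD2 gave a ratio of 33.5 (95% exact interval 8.93 to 282), on 2 counts over the tapinarof group. FKBP5 measured 0.22 (adjusted p = 0.188) and AHR 0.31 (0.257). G2/M genes passed downward at 7.81e-09 (adjusted p = 0.119 with an estimated correlation), with 10 of 30 down and 0 up (21 and 0 over the list alone). Androgen-induced genes passed upward at 6.58e-08 (adjusted p = 0.119 with an estimated correlation), with 14 up and 1 down of 41 (18 and 2 over the list alone). Androgen-repressed genes passed downward at 0.00128 (adjusted p = 0.173 with an estimated correlation), with 6 down and 1 up of 16 (8 and 1 over the list alone). With trends removed 22 androgen-induced genes rose and 3 fell. Another 4 lists passed with all libraries and not without tapinarof library 1. These were AHR targets at 0.00848 (0.0521 without that library) and fatty acid synthesis at 0.00927 (0.148, and 0.131 with length and GC trends removed), both upward, sterol synthesis upward at 0.0336 (0.151, and 0.131 without combination library 1), and G1/S genes downward at 0.000286 (0.0521). With an estimated correlation their adjusted p was 0.173, or 0.276 for fatty acid synthesis. In all, edgeR called 1500 genes, 833 up and 667 down. The count was 2826 without tapinarof library 1, 633 and 357 without combination library 1 or 2, 481 when only the groups compared were fitted and 2815 with trends removed.

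Tapinarof was compared in the same way within RBN-2397-treated cells, the combination against DHT with RBN-2397. CYP1A2 rose by 4.02 (SE 0.22) and CYP1A1 by 2.13 (SE 0.15), and ALDH1A1 fell by 1.82 (SE 0.13), from 62.2 ± 0.815 to 17.6 ± 0.401 CPM (mean ± SD, n = 2). KLK3 rose by 0.75 (SE 0.14, adjusted p = 0.0349), TIPARP by 0.61 (SE 0.11, 0.0257) and the monooxygenase gene CYP1B1 by 1.03 (SE 0.18, 0.0257). KLK2 measured 0.31 (0.373), AHRR 0.68 (0.231) and NQO1 -0.34 (0.277). G2/M genes passed downward at 4.47e-15 (adjusted p = 0.0660 with an estimated correlation), with 0 of 30 past edgeR over all genes, 13 down over the list alone and 2 down over all genes with trends removed. AHR targets passed upward at 4.64e-05 (adjusted p = 0.0802 with an estimated correlation), with 5 of 16 up and 0 down (6 and 1 over the list alone). Androgen-induced genes passed upward at 0.00523 and the stress response list downward at 0.000605 (both adjusted p = 0.340 with an estimated correlation). Androgen-repressed genes passed downward at 0.000139 (adjusted p = 0.184 with an estimated correlation) and G1/S genes downward at 0.0103 (adjusted p = 0.375 with an estimated correlation; 0.0518 without RBN-2397 library 2). In all, edgeR called 60 genes, 51 up and 9 down. The calls of KLK3 and TIPARP ended without either library of DHT, of RBN-2397 or of the combination (adjusted p from 0.0602 to 0.487), and that of CYP1B1 without either library of RBN-2397 or of the combination (0.181 to 0.30). A fit with replicate number as a block ended those of TIPARP (0.0600) and CYP1B1 (0.0528). The DHT libraries are not compared here and enter only through the shared fit. By library, KLK3 held 68.2 and 69.4 CPM with RBN-2397 and 115.5 and 116.4 with the combination. TIPARP held 113.4 and 108.8 CPM with RBN-2397 and 169.3 and 169.0 with the combination. The count was 32 without either DHT library, 10 and 5 without RBN-2397 library 1 or 2, 10 and 9 without combination library 1 or 2, and 271 and 296 without tapinarof library 1 or 2. It was 38 with the block, 137 with the DESeq2 test, 106 with no filter, 1039 when only the groups compared were fitted, and 245 with trends removed.

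The difference between the compounds was tested directly, RBN-2397 in DHT against tapinarof in DHT. KLK3 was higher with RBN-2397 by 1.88 (SE 0.15) and TIPARP by 1.45 (SE 0.11), as were the carboxylesterase CES4A by 3.61 (SE 0.52), SCNN1G by 3.53 (SE 0.22) and TUBA3D by 3.23 (SE 0.18; n = 2 per group). CYP1A2 was lower with RBN-2397 by a log2 fold change of -2.12 (SE 0.23). CYP1A1 differed by 0.23 (SE 0.15, adjusted p = 0.618), with means of 55.9 ± 0.272 CPM with RBN-2397 and 47.8 ± 13.3 CPM with tapinarof. Androgen-induced genes were higher with RBN-2397 (11 of 41 passed and 0 were lower, 14 and 0 over the list alone; camera adjusted p = 6.5e-10; adjusted p = 0.0705 with an estimated correlation). Sterol synthesis genes were higher at 7.52e-06 (median 0.22; adjusted p = 0.0511 with an estimated correlation), with 0 of 23 past edgeR over all genes or over the list alone, and 6 higher with trends removed. Another 4 lists passed, each until 1 tapinarof library was left out. Fatty acid synthesis at 0.00198 and p53 targets at 0.0206 were higher and G1/S genes at 0.00635 lower with RBN-2397, but not without library 1 (0.113, 0.144 and 0.269). The stress response list was higher at 3.78e-05, but not without library 2 (0.108). With an estimated correlation these gave an adjusted p of 0.286, 0.192, 0.319 and 0.238. In all, edgeR called 236 genes, 200 higher and 36 lower with RBN-2397. The count was 108 and 103 without RBN-2397 library 1 or 2, 1085 without tapinarof library 2, 84 when only the groups compared were fitted, and 825 (559 higher and 266 lower) with trends removed.

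The interaction asked whether the effect of RBN-2397 differed with and without tapinarof. By gene, edgeR called 0 of 13248, with 836 at an unadjusted p under 0.05, where chance gives 662, and DESeq2 called 10. ALDH1A1 came closest at -1.25 (adjusted p = 0.0783). KLK3 measured 0.82 (adjusted p = 0.555), TIPARP 0.48 (0.766), CYP1A1 -0.92 (0.555), CYP1B1 0.79 (0.766), AHRR 0.71 (0.781), KLK2 0.27 (0.815) and NQO1 -0.35 (0.781). By list, 6 passed camera: androgen-induced genes (median 0.08) and fatty acid synthesis (0.11) upward, and androgen-repressed genes (-0.29), G1/S genes (-0.12), G2/M genes (-0.17) and the stress response list (-0.21) downward. With an estimated correlation each had an adjusted p of 0.292, and with length and GC trends removed fatty acid synthesis did not pass (0.159) and the G2/M median was -0.11. The count of genes was 1 with no filter, 5 and 137 without tapinarof library 1 or 2, and 19 with trends removed, among them ALDH1A1 at -1.09 (adjusted p = 0.00725) and the serine synthesis enzyme PHGDH at -0.69 (0.00867), named after their values were seen.

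The effects of RBN-2397 with and without tapinarof were set side by side, in comparisons that share no library. Of its 175 rises in DHT, 170 were among the 833 rises within tapinarof-treated cells, where chance gives 11, and of its 24 falls 21 were among the 667 falls there, where chance gives 1.21. Across genes the log2 fold changes of these comparisons correlated at r = 0.58. DHT against vehicle and RBN-2397 within tapinarof-treated cells moved 253 genes up together (53.5 by chance) and 143 down (57.4 by chance), at r = 0.21. Another 67 rose with DHT and fell with RBN-2397 (42.8 by chance), and 45 fell with DHT and rose with RBN-2397 (71.7 by chance). STEAP4 and KLK3 rose in both, while FKBP5 rose by 2.98 with DHT and measured 0.22 with RBN-2397. CYP1A1 and CYP1A2 were the 2 genes that rose with tapinarof in both settings, at r = 0.12 across genes. DHT and tapinarof added to RBN-2397 raised 20 genes together (3.28 by chance) and lowered 3 (0.774 by chance), at r = 0.025. Another 5 rose with DHT and fell with tapinarof (0.578 by chance), and 11 fell with DHT and rose with tapinarof (4.39 by chance). The chance values treat all genes as equally likely to be called. They may be too low, since here opposite calls exceeded them too, and the excess of shared calls may be overstated. Where comparisons share libraries, r was 0.29 for RBN-2397 with tapinarof (0.49 in simulated data with no change). It was 0.12 for DHT with RBN-2397 (-0.50 simulated) and -0.18 for DHT with tapinarof (-0.49 simulated). Real changes widen the spread of fold changes, so these r values cannot be read against those simulated with no change. The covariance was 0.0354 for RBN-2397 with tapinarof (0.0299 simulated), 0.0272 for DHT with RBN-2397 (-0.0304) and -0.0343 for DHT with tapinarof (-0.0298). The simulated data used a spread per gene shared by all groups, to which the wider vehicle and tapinarof pairs contribute. For the shared DHT group the simulated values may thus be too large in size, so small differences from them cannot be read. The 170 shared rises became 80 and 75 without DHT library 1 or 2, 93 and 96 without RBN-2397 library 1 or 2, and 293 and 270 without tapinarof library 1 or 2; the 253 became 167 and 160 without DHT library 1 or 2, 381 without tapinarof library 2, and 164 and 142 without combination library 1 or 2. The smaller overlaps and correlations moved further: the 20 became 10 and 9 without DHT library 1 or 2, 2 and 1 without RBN-2397 library 1 or 2, 76 and 87 without tapinarof library 1 or 2, and 3 and 2 without combination library 1 or 2, the 2 became 30 without tapinarof library 2, and r for DHT with RBN-2397 turned to -0.107 and -0.141 without DHT library 1 or 2.

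**Figure D4:**
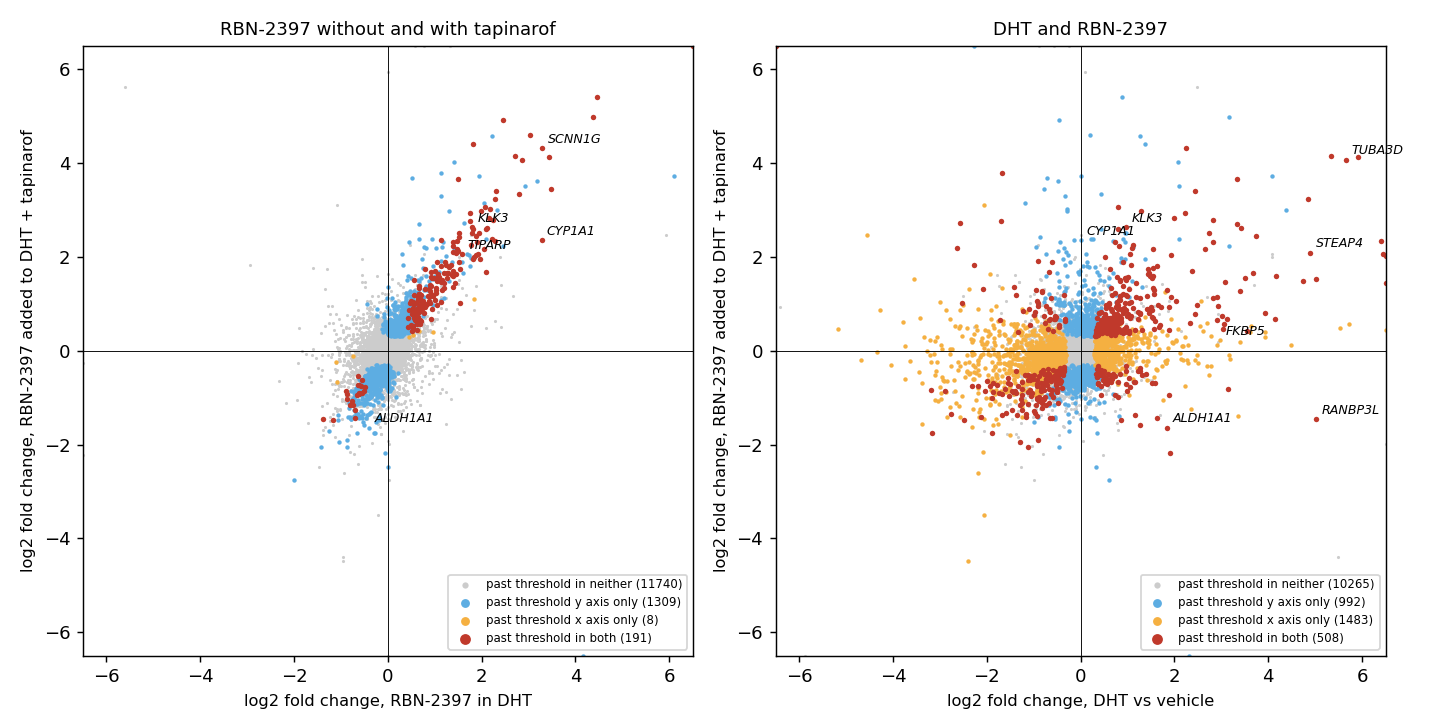
Log2 fold change of each tested gene, 1 point per gene coloured by the test it passed, for RBN-2397 added to tapinarof (vertical axes) against RBN-2397 in DHT (left panel) or DHT against vehicle (right panel), with values beyond 6.5 drawn at the edge and values of genes with 3 counts or fewer in a group depending on the fit. The 170 genes that rose in both lie at the upper right of the left panel, with KLK3 at 1.80 and 2.63.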

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

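Among the tests given here, the wrong-label test, the test of AHR activation alone and the removal of length and GC trends were chosen only after the result was seen.

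The effect of RBN-2397 differed with and without tapinarof for 6 gene lists by the interaction test in camera, where it differed for 0 single genes in edgeR (836 at an unadjusted p under 0.05; 10 genes in DESeq2; 5 and 137 in edgeR without tapinarof library 1 or 2, and 19 with trends removed). None of the 6 passed with an estimated correlation (adjusted p = 0.292 for each) or in fry (0.207 for each). With the preset correlation G2/M mitotic genes were lower than the separate effects add up to (adjusted p = 3.3e-06, median -0.17; 0.000153 and -0.11 with trends removed), as were G1/S replication genes (0.00197, -0.12), the stress response list (0.000834, -0.21) and androgen-repressed genes (0.00784, -0.29). Androgen-induced genes (0.00661, 0.08) and fatty acid synthesis genes (0.00661, 0.11) were higher. Without tapinarof library 1 the calls of androgen-induced genes (0.332), G1/S genes (0.233), fatty acid synthesis (0.332) and the stress response (0.233) ended, while G2/M (4.36e-06) and androgen-repressed genes (0.0239) passed. Without tapinarof library 2 that of androgen-repressed genes ended (0.270), and with length and GC trends removed that of fatty acid synthesis (0.159).

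The libraries with tapinarof differed from each other more than those of any other group did (SD of their log2 ratio 0.42, against 0.28 to 0.33). A wrong label on library 1 is argued against by CYP1A1, which stood 6.665-fold above the DHT mean there and 9.92-fold in library 2, while KLK3 was at 0.864-fold in library 1. A bias with transcript length had the trend it needs, with a rho of -0.5002 across genes, against -0.22 to 0.31 in the other pairs. GC content stays open: its rho was 0.5988, but the vehicle pair reached -0.62 with closer agreement between its libraries. Removing both trends took the SD from 0.42 to 0.34, still above the 0.27 to 0.28 of the other groups, so they may account for a part of the spread, and no biological explanation was tested.

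Tapinarof changed 2 genes in DHT (6 and 1117 without tapinarof library 1 or 2, 6 with trends removed) and 60 when added to RBN-2397 (32 without either DHT library, 10 and 5 without RBN-2397 library 1 or 2, 271 and 296 without tapinarof library 1 or 2, 10 and 9 without combination library 1 or 2, 245 with trends removed). Over the 58 genes of the second comparison besides CYP1A1 and CYP1A2, 69% moved the same way with tapinarof alone, 60.3% by library 1 and 81% by library 2, where random lists give 50% at the median and 62.1% at the upper end of their central 95%. The spread between the tapinarof libraries cannot be told apart from a smaller effect of tapinarof alone by this share. It lies between the bounds set for either reading, near the lower one by library 1 and above the upper one by library 2. The reading of hidden changes also required a minimum median change, which was not met. In the direction of the second comparison, where these 58 genes were chosen, the median was 0.14 with tapinarof alone and 0.80 when it was added to RBN-2397. With tapinarof alone it was 0.139 by library 1 and 0.123 by library 2. Gene counts without tapinarof library 2 rest on library 1 for that group, where a length trend cannot be told apart from an effect. The interaction test called 0 genes in edgeR (836 at an unadjusted p under 0.05; 10 called in DESeq2), but 5 and 137 without tapinarof library 1 or 2 and 19 with trends removed, ALDH1A1 (adjusted p = 0.00725), PHGDH (0.00867) and ANXA2 (0.0395) among the 19, so a difference for single genes depends on the fit.

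RBN-2397 raised 173 genes in DHT besides CYP1A1 and CYP1A2, by a median of 0.99. AHR activation of the extent that tapinarof alone gave is argued against as the cause, since with tapinarof alone those genes had a median of 0.0052 (quartiles -0.10 to 0.17). In edgeR, CYP1A1 and CYP1A2 were the only genes that tapinarof alone raised. The comparison therefore cannot decide on a wider activation of AHR, such as where PARP7 is inhibited. Tapinarof added to RBN-2397 moved the same 173 genes by a median of 0.43 (1.34 with the combination against DHT), so a part played by AHR once PARP7 is inhibited stays open. A general rise of the androgen response stays open: of 20 androgen-induced genes that DHT raised 2-fold or more, 25% were below 0 with RBN-2397 added to tapinarof, and 7 rose and 0 fell, with a median of 0.30. KLK3 and KLK2, which DHT raised by just under 2-fold, are outside the 20, and both rose with RBN-2397 added to tapinarof. Reads shared between paralogs and a second target of the compound were not tested here.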

How the results depend on the processing

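All 10 libraries hold 13419660 to 15722502 counts, so genes with few counts in a group carry wide intervals, and 2 libraries per group limit the calls. The main fit also shares its estimate of spread over all groups. The wider disagreement of the tapinarof pair (SD of log2 ratio 0.42) thus enters every comparison, also those without tapinarof, and the counts of calls depend on it. Counts were deposited, so no pseudocount or normalized-value alternative applies. Each library left out leaves 1 in its group, which is assumed to vary like the others. Of 215 named gene results past the threshold, 120 kept their call and direction in the 14 alternatives run for named genes (DESeq2 size factors, the DESeq2 test, no filter, the block and each of 10 libraries left out), 0 of 334 results reversed in these, and all 215 kept their call with length and GC trends removed. That removal was chosen after seeing the data. It fitted trends to the deviation of each library from the mean of all libraries, so trends caused by a treatment would be removed too. It also lowered the estimated spread, which makes calls easier to keep, so the kept calls are not an independent check. All 53 list calls were kept with DESeq2 size factors and with the replicate block, 2 were kept with an estimated correlation, 15 ended without tapinarof library 1 and 6 without library 2, and at most 2 without any other library. With trends removed 50 of the 53 were kept, the 3 of fatty acid synthesis for tapinarof (camera adjusted p = 0.0655), RBN-2397 added to tapinarof (0.131) and the interaction (0.159) ended, 1 was added (G1/S genes for RBN-2397, 0.0111), and 12 passed with an estimated correlation, such as G2/M (0.0289) and androgen-induced genes (0.0289) for the combination. Replicate numbers showed no clear pairing of samples: over 10 pairs of groups the correlation of residuals ran from -0.21 to 0.21, with 1 above 0.1. The length and GC trends within each group enter these values, so a paired preparation is not excluded.

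The DESeq2 test gave 4 genes for tapinarof, 137 for tapinarof added to RBN-2397 and 10 for the interaction. No filter gave 106 for tapinarof added to RBN-2397 and 1 for the interaction. The replicate block gave 38 for tapinarof added to RBN-2397. Fits of only the groups compared, on fewer samples, gave 1005 for RBN-2397, 4638 for the combination, 481 for RBN-2397 added to tapinarof, 1039 for tapinarof added to RBN-2397 and 84 for the difference between the compounds. Removing trends gave 3857 genes for DHT, 598 for RBN-2397, 6 for tapinarof, 2601 for the combination, 2815 for RBN-2397 added to tapinarof, 245 for tapinarof added to RBN-2397, 825 for the difference and 19 for the interaction, and kept 1990, 198, 2, 1450, 1379, 60, 235 and 0 of the calls. It took the biological coefficient of variation from 9.4% to 5.99%. The stricter filter, which tests fewer genes, gave r = 0.754 for RBN-2397 without and with tapinarof and 0.214 for tapinarof without and with RBN-2397.

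Leaving out each library gave 966 to 3002 genes for DHT, 76 to 433 for RBN-2397, 2 to 1117 for tapinarof, 397 to 3184 for the combination, 357 to 2826 for RBN-2397 added to tapinarof, 5 to 296 for tapinarof added to RBN-2397, 103 to 1085 for the difference and 0 to 137 for the interaction. The interaction's 0, from edgeR, stands beside 836 genes at an unadjusted p under 0.05 and 10 in DESeq2. For RBN-2397 without and with tapinarof, r ran from 0.421 to 0.539 and the shared rises from 75 to 293. For tapinarof without and with RBN-2397 they ran from 0.0110 to 0.189 and from 2 to 30. For DHT with RBN-2397 added to tapinarof they ran from 0.147 to 0.292 and from 142 to 381, and for DHT with tapinarof added to RBN-2397 from -0.0241 to 0.0733 and from 1 to 87. In comparisons that share libraries, r ran from 0.159 to 0.535 for RBN-2397 with tapinarof, from -0.376 to -0.126 for DHT with tapinarof, and from -0.141 to 0.140 for DHT with RBN-2397. The last changed sign, to -0.107 without DHT library 1 and -0.141 without library 2, where the shared group has fewer samples. With all libraries the value simulated with no change was -0.50, so 0 is not the reference for this pair. No value was simulated for the fits with a library left out. Leaving out a library also changes which genes pass the filter, and beyond that the cause was not tested. Without tapinarof library 2, that group rests on library 1, where a length trend cannot be told apart from an effect of tapinarof.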

Other observations

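Among the tests given here, the removal of length and GC trends was chosen only after the result was seen, and so were the gene families named.

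Of 8 tested genes of the HOXB homeobox cluster, 7 fell and 0 rose with the combination, with a median of -1.02, such as HOXB5 at -1.30 (SE 0.24), HOXB6 at -1.32 (SE 0.17) and HOXB9 at -1.07 (SE 0.19; n = 2 per group). With RBN-2397 added to tapinarof 7 fell (median -0.95), and 4 without either combination library. With RBN-2397 alone 1 fell, HOXB6 at -0.81 (SE 0.16), though the median of the 8 was -0.62. With tapinarof alone 0 of 8 passed edgeR (median 0.095), where DHT alone lowered 3 (median -0.53). In the interaction 0 of 8 passed (median -0.39), so the counts of calls do not show a fall particular to the combination. For the combination 6 fell with DESeq2 size factors and 7 with length and GC trends removed, 4 without either DHT library, 6 without either RBN-2397 library, 3 without combination library 1 and 5 without library 2, with medians from -0.95 to -1.14. For RBN-2397 alone 5 fell with trends removed, and 0 did so without any 1 of its own or the DHT libraries in edgeR.

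The epithelial sodium channel subunits SCNN1G and SCNN1B rose with the combination by 4.08 (SE 0.20) and 3.54 (SE 0.26), while SCNN1A, the remaining member tested, measured 0.03 (adjusted p = 0.921); the same count of 2 rose with DESeq2 size factors, with trends removed and without each library. ANXA2, which encodes a membrane-binding annexin, rose by 2.17 (SE 0.14) with RBN-2397 and 2.97 (SE 0.14) with the combination. IL1R1 rose by 0.96 (SE 0.11) and 1.61 (SE 0.11) in the same comparisons, and the growth factor binding protein IGFBP3 by 0.58 (SE 0.10) and 1.26 (SE 0.10). Of 9 genes of serine and one-carbon synthesis, 4 fell and 0 rose with the combination, PHGDH at -0.58 (SE 0.11), PSAT1 at -0.52 (SE 0.10), MTHFD2 at -0.55 (SE 0.11) and ALDH1L2 at -0.50 (SE 0.13). No test of this set as a whole was run, and the count was 0 without DHT library 2 or combination library 2, 2 without DHT library 1, and 6 with trends removed or without tapinarof library 1. Of 82 ribosomal protein genes 5 fell and 0 rose with DHT (median -0.25), 36 fell and 1 rose with trends removed, 35 fell and 1 rose without either tapinarof library, 1 fell without vehicle library 1 or either RBN-2397 library, and 0 passed without either DHT library in edgeR.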
